A study of Mus musculus with 12 samples.

How the data were processed

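Gene expression was measured with a 1-colour Illumina array in 12 mice. Per the labels' protocols, total RNA came from a whole piece of the proximal small intestine, so that epithelium, stroma, muscle, blood and immune cells were read together, and biotin-labelled cRNA was made with the Ambion Illumina TotalPrep kit. The samples were labelled P6 and came from a mixed C57/BL6;129Ola background. Group and replicate number were taken from the sample titles, which gave 6 control mice and 6 mutant mice. The mutants were described as villinCre;Shp2fl, meaning that a Cre recombinase expressed in the intestinal epithelium acts on a loxP-flanked allele of Ptpn11, the gene of the tyrosine phosphatase Shp2. The labels call the samples biological replicates and the design text counts mice, so n is the number of mice.

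The deposited values were intensities on a linear scale, 1 value for each of 18090 gene symbols and each mouse. Per the submitters' processing notes, GenomeStudio and Partek were used, with no version and no role given. The deposited intensities themselves show what else had been done: 22.5% of them lay below 0, which background subtraction leaves, and the 12 columns had nearly the same distribution, with medians from 41.8 to 43.4 and a highest value of 40554.2. Whether the probes of a gene were averaged or selected, and the array version, were not given in the sources used here. A second table held 24 columns of per-sample values whose headings matched no sample label. Those columns, with their detection p-values, were not used here.

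The design fixed before the data were examined had assumed non-normalized signals with detection p-values. Because the usable values were background-subtracted and normalized already, the fallback written in that design was followed. The deposited intensities were passed through normexp with an offset of 50 fitted on all rows, quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. All rows were kept, since no detection p-value could be tied to a mouse. Quantile normalization forces the arrays to 1 distribution, so a shift of all genes together would not be seen. The offset shrinks the log2 difference of dim genes, and for these the fold of the deposited means is larger than the fitted one. The size of the most negative deposited value, 27.8, served as a noise limit, and 7888 rows (43.6%) had both group means at or under it. Where every mouse of 1 group lay at or under the limit and every mouse of the other above it, the fold is given as a lower bound, the geometric mean of the higher group over the limit. For arrays, the number of mice limits the precision.

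Mutant and control were compared with limma (lmFit and eBayes, group as the only term, two-sided) and Benjamini-Hochberg adjustment over all rows, with a threshold at an adjusted p of 0.05. Folds of 1.5 and 2 were asked for in further counts. Ptpn11 was also tested with an exact permutation test over all 924 assignments. For gene lists, 33 were fixed before the data were examined, covering the cell types of the intestine, other cell types that such a piece of tissue could hold, signalling outputs, and metabolic and stress programmes. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, at least 4 measured members, and 1 row per gene (the brightest). Changed genes within 50 annotated genes on each side of Ptpn11 and of Vil1 were compared with all others by a two-sided Fisher's exact test.

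Row names were older symbols in upper case. They were matched to the gene table of assembly GRCm38.p6 for current symbols and gene order only: 14090 rows matched by symbol and 3025 by a single synonym, 75 were ambiguous, 879 matched none, and 21 had been turned into dates or numbers. Symbols are printed as the table gives them, with the current symbol where it helps.

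The genes named in the text followed a rule written in advance: Ptpn11, Lyz1, Mmp7, Muc2, Tff3, Spdef, Klf4, Atoh1, Lgr5, Olfm4, Axin2, Tcf7l2, Ctnnb1, Dusp6, Spry2, Chga, Vil1 and Mki67 where they had a row (Muc2 and Mki67 had none that matched), the 12 named genes with the largest change past the threshold in each direction by log2 difference, up to 4 members of each list past the camera threshold or with at least 3 members past the gene threshold, and up to 2 of every other list. Genes chosen after their values were seen are said to be so, and so were chosen the members named as passing only when adjusted over their list alone.

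On simulated data built from the 12 arrays with 18090 genes, of which 200 were changed, the mutant versus control fit recovered 76.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 2.65% of its calls were unchanged genes. No list was called with nothing changed, and 1 was called when 1 list was shifted by 0.5 on the log2 scale. The changed genes were drawn from rows with a mean above the noise limit, so the recovery does not cover dim rows. Noise was drawn for each gene independently, so false calls of lists whose members vary together were not assessed. In the data such correlation was estimated at 0.405 for the Paneth cell list and 0.449 for interferon response. Alternatives changed the background correction, the normalization, the spread estimate, array weights, the replicate number as a block, sex as a covariate, the correlation within lists, the set test, and the mice included. The fit without background correction also had no offset, and deposited values under 1 were set to 1 in it. Sex was read from Xist and Y-linked genes: 4 male and 2 female mice were found in each group. An offset of 16, a filter at the noise limit and the removal of control 4 with mutant 1 were added after seeing the data. Python 3.11.15 and matplotlib 3.10.9 drew the figures.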

Results

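Intestinal gene expression was compared between 6 control mice and 6 mice in which the floxed Ptpn11 allele was exposed to villin-driven Cre recombinase. The question, as the series title and design put it, was which transcripts of the small intestine differ when Shp2 is targeted in the epithelium. Shp2 is a tyrosine phosphatase that relays receptor signals to the RAS and ERK pathway. Group means are deposited array intensities in arbitrary units, given as mean ± SD over 6 mice, and log2 differences (mutant minus control) with their SE come from limma on the offset log2 scale. Arrays correlated at 0.983 to 0.994 within groups and at 0.973 to 0.987 between groups. The first principal component held 39.1% of the variance and separated the groups, while the second held 13.9% and set control 4 and mutant 1 apart from the rest. Both of those samples carried high levels of pancreatic acinar transcripts, with Ela2a, a pancreatic elastase chosen here after its values were seen, at 16839.6 in control 4 and 7043.9 in mutant 1.

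Ptpn11, the targeted gene, was not lower in the mutants. Its intensity was 1288 ± 124 in controls and 1498 ± 119 in mutants, a log2 difference of 0.21 (SE 0.07) that did not pass the threshold (limma adjusted p = 0.0763). The exact permutation test over 924 assignments gave p = 0.0152 (two-sided, smallest possible 0.00216), with all 6 mutants above the control mean. Without control 3 the difference was 0.25 and passed the threshold (adjusted p = 0.043). The position of the array probe on the transcript is not given in the sources used here, so this row does not check the labels. Vil1, whose promoter drives the Cre, read 9101 ± 1121 in controls and 8714 ± 990 in mutants (adjusted p = 0.801).

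**Figure D1:**
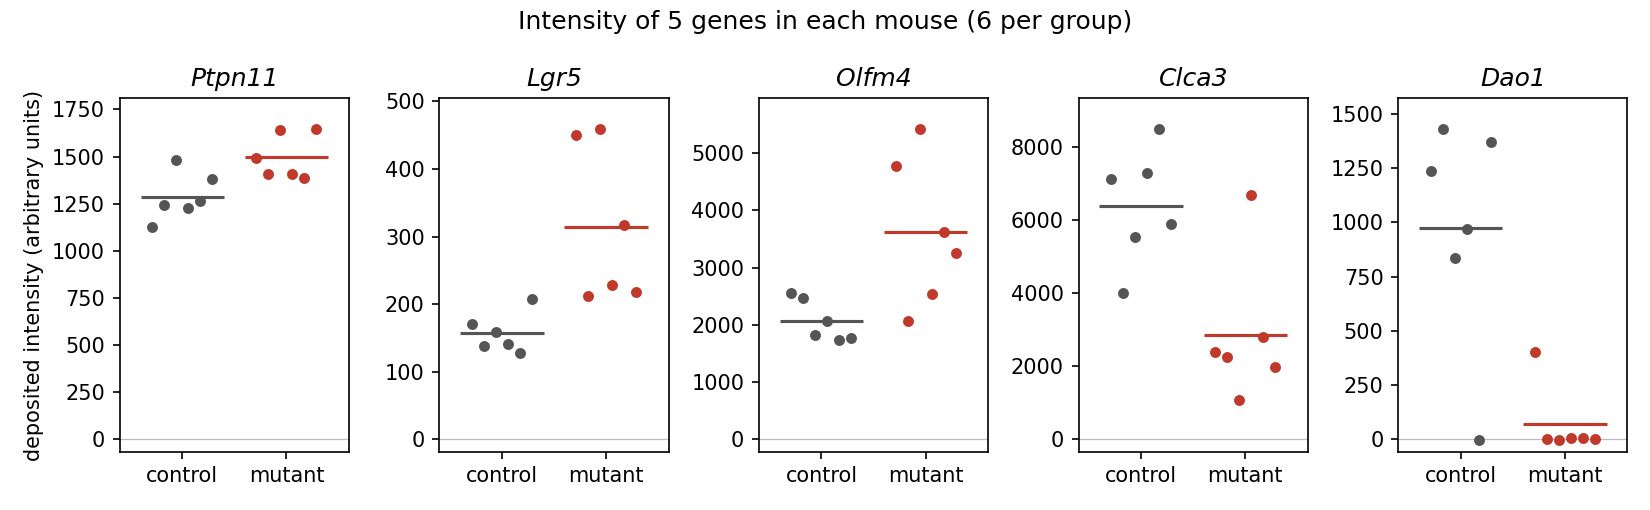
Deposited intensity (y axis, arbitrary units, a separate scale for each gene) of Ptpn11, Lgr5, Olfm4, Clca3 and Dao1 in each of 6 control (grey) and 6 mutant (red) mice, with points for mice and lines for group means. Ptpn11 means were 1288 and 1498, and Dao1 lay near 0 in 5 mutants and in control 5.

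Of 18090 rows, 1663 (9.2%) passed the threshold, 852 higher and 811 lower in the mutants. At least a 1.5-fold change was seen in 431 of them (246 higher, 185 lower) and at least a 2-fold change in 138, of which 102 were higher and 36 lower. Without background correction, and so without the offset, these counts were 697 and 317. The values of 846 rows (4.7%) did not overlap between the groups, against 0.2165% by chance. Among the genes named by the rule, Reg3b, a secreted antimicrobial lectin of the epithelium, had the largest rise in log2 difference (6.78, SE 0.17, limma adjusted p = 1.25e-11). It went from 77.7 ± 36.2 to 16210 ± 3019, or 208.5-fold on the deposited scale. The cystatin-family protease inhibitors Stfa1 and Stfa2 rose from 103.4 ± 32.0 to 3465 ± 1512 and from 29.3 ± 9.9 to 1495 ± 667. The largest falls were smaller. Aqp8, a water channel, fell from 2183 ± 399 to 624.8 ± 63.1 (log2 difference -1.68, SE 0.11), Apoc1, an apolipoprotein, from 723.0 ± 261.6 to 179.0 ± 73.3, and Abhd5, an activator of triglyceride breakdown, from 837.7 ± 160.3 to 251.2 ± 124.8. Ctsl, a lysosomal protease, fell from 727.5 ± 318.7 to 202.9 ± 82.8, Serpina1a, a protease inhibitor, from 697.9 ± 200.3 to 203.4 ± 63.6, Ptgds2 (Hpgds, a prostaglandin synthase) from 369.3 ± 112.3 to 103.4 ± 34.0, and Zdhhc19 from 346.0 ± 69.2 to 102.4 ± 37.2. Dao1 (today's Dao, D-amino acid oxidase) had the largest fitted fall, -2.89 (SE 0.70, adjusted p = 0.0181), but its levels did not follow the groups throughout. It read -0.7 in control 5 against 837.6 to 1430.4 in the other controls, and 402.8 in mutant 1 against -1.3 to 8.8 in the other mutants. Its call ended with array weights (log2 difference -2.47, adjusted p = 0.0562), with trend and robust variances (-2.89, 0.0552) and without background correction (-5.79, 0.137), where the fitted fall was larger.

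Paneth cell genes rose together and to high levels. Paneth cells are the antimicrobial cells of the crypt base. Of 18 measured list members, 12 rose and none fell (camera adjusted p = 2.26e-22, and adjusted p = 0.0499 with an estimated correlation), and 14 passed when adjusted over the list alone. Lyz1, the Paneth cell lysozyme, rose from 129.9 ± 56.8 to 6832 ± 3377 (log2 difference 4.97, SE 0.32). The row Lyz, matched to the same gene by synonym only, rose from 4101 ± 1108 to 20970 ± 5476 and, being brighter, stood for it in the list. Its control level was far above that of the Lyz1 row, and whether it reads Lyz1 alone was not tested. The alpha-defensins Defcr5 and Defcr26 rose from 102.4 ± 109.0 to 10940 ± 5102 and from 108.2 ± 76.4 to 7138 ± 3451, and AY761184, of the same family, from 40.9 ± 24.4 to 1509 ± 646. Itln1, an intelectin, rose from 112.3 ± 82.2 to 2761 ± 1169 and Reg3a from 71.0 ± 22.6 to 1896 ± 592. Reg3g was within the noise limit in controls (3.3 ± 7.9) and read 5767 ± 2931 in mutants, at least 171.2-fold higher. Mmp7, a defensin-processing protease, rose from -4.1 ± 3.2 to 31.3 ± 15.5 (log2 difference 0.60, SE 0.09, adjusted p = 0.000991), with mutants 2 and 4 under the noise limit. Since transcripts of near-identical defensins can bind one another's probes, single members are uncertain. The alpha-defensin rows Defcr4, Defcr6 and Defcr20 were not matched to list members by symbol, and so were not counted. Looked at afterwards, Defcr6 and Defcr20 rose (limma adjusted p = 0.00229 and 4.41e-07) and Defcr4 did not pass (0.832). The 9 list members outside that family, among them Reg3g, which the defence list also holds, gave a camera adjusted p of 1.61e-13 at the preset correlation. No value with an estimated correlation is given for these 9. Mutant 4 had the lowest mutant values of Lyz1 (2462.3), Reg3b (11129.3) and Defcr5 (3720.9), all above every control.

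**Figure D2:**
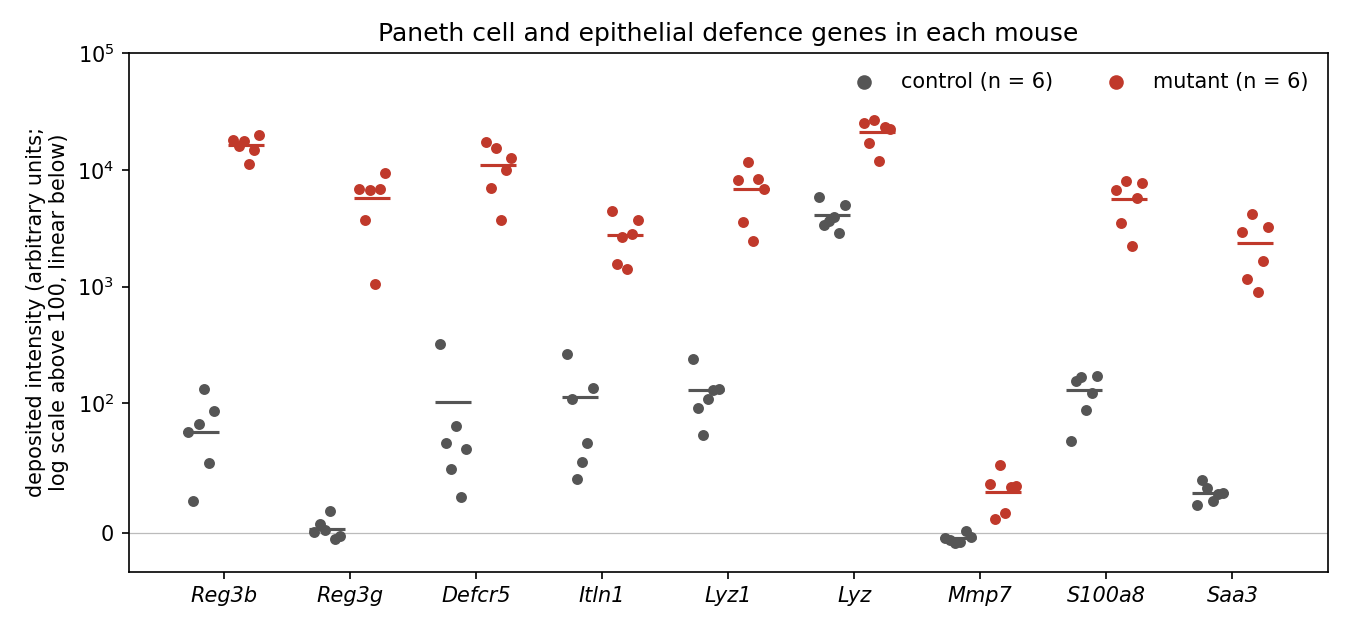
Deposited intensity (y axis, arbitrary units, log scale above 100 and linear below) of 9 Paneth cell and epithelial defence genes in each of 6 control (grey) and 6 mutant (red) mice, with points for mice and lines for group means. Reg3b averaged 77.7 in controls and 16210 in mutants, and for each of the 9 genes every mutant lay above every control.

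Genes of epithelial defence and inflammation rose as well. In the list of 25 measured members, 14 rose and none fell (camera adjusted p = 5.05e-15, adjusted p = 0.0662 with an estimated correlation), and 16 higher and 1 lower (Tnfaip3) passed when adjusted over the list alone. Reg3b and Reg3g belong here, the latter also being in the Paneth cell list. The calcium-binding protein S100a8 rose from 130.6 ± 41.8 to 5650 ± 2325 and its partner S100a9 from 31.4 ± 13.7 to 1428 ± 642, and the acute-phase protein Saa3 from 30.5 ± 6.9 to 2345 ± 1308. The neutrophil list shares S100a8, S100a9 and Il1b with it. Of its 13 members 6 rose and none fell (camera adjusted p = 5.38e-08, adjusted p = 0.0786 with an estimated correlation), and 6 higher and 1 lower (Mmp9) passed when adjusted over the list alone. Ltf, lactoferrin, rose from 48.5 ± 5.7 to 161.5 ± 45.9 and Retnlg, a resistin-like protein of neutrophils, from 80.3 ± 38.3 to 421.3 ± 203.6. Blood markers did not move the same way: of 11 erythroid genes, 3 fell and none rose (camera adjusted p = 0.0672). Haemoglobin Hba-a1 fell from 23510 ± 3798 to 15500 ± 3021, Hbb-b2 from 433.1 ± 219.2 to 116.7 ± 74.4 and Eraf, a haemoglobin chaperone, from 96.4 ± 30.8 to 43.4 ± 20.1, a call that ended without background correction (adjusted p = 0.0588). That list passed its threshold without control 1 (adjusted p = 0.0216) or without mutant 4 (0.017).

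**Figure D3:**
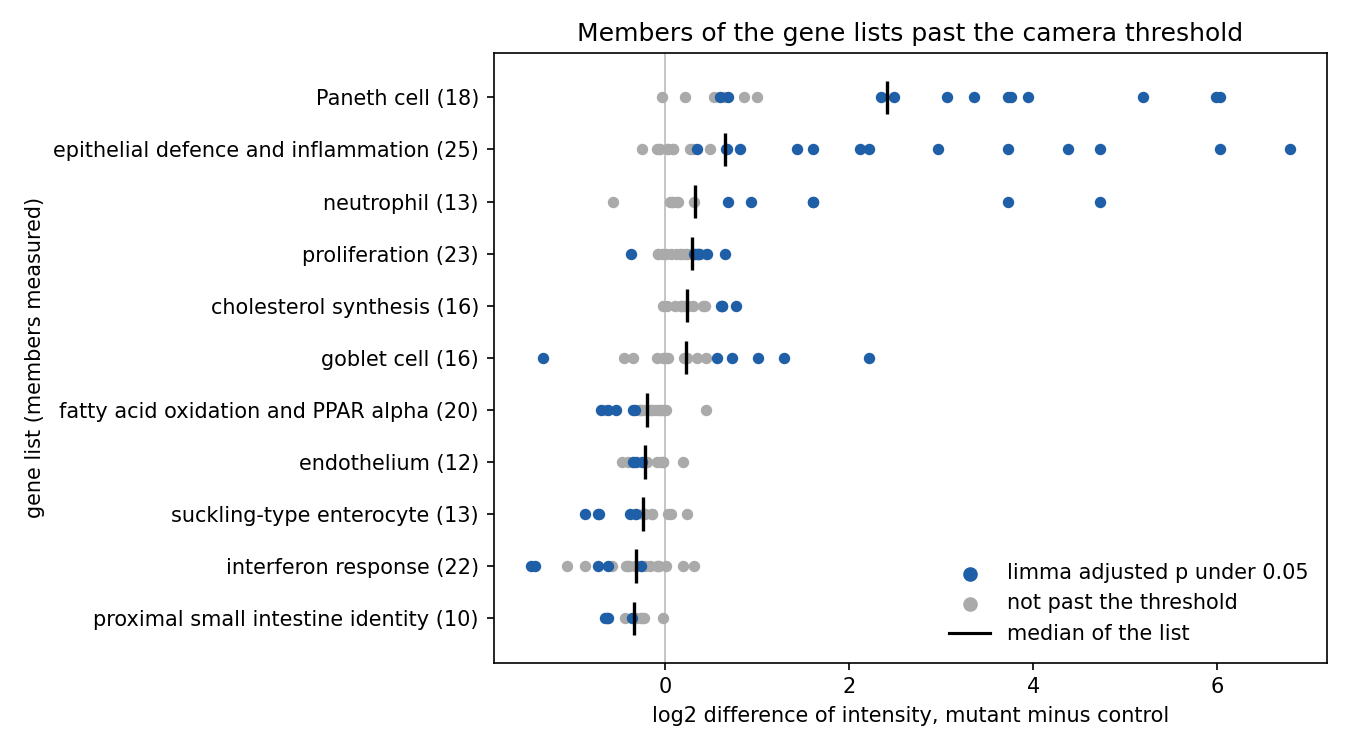
Log2 difference (x axis, mutant minus control) of each measured member of the 11 gene lists past the camera threshold (y axis, with the number of members), blue for members past the limma threshold and grey for the others, with black bars for the list medians. The Paneth cell list had a median of 2.41, and 5 of the 11 lists had medians below 0.

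Goblet cell genes split. Goblet cells secrete the intestinal mucus. Among 16 members 5 rose and 1 fell (camera adjusted p = 0.0026, adjusted p = 0.158 with an estimated correlation), with 7 higher and 2 lower adjusted over the list alone. Spink4 rose from 4620 ± 932 to 11480 ± 2106, Guca2a, the precursor of guanylin, from 2776 ± 461 to 5680 ± 935, and the chemokine Ccl6 from 279.1 ± 70.5 to 505.2 ± 94.8. Retnlb, an antibacterial protein, was within the noise limit in controls (0.95 ± 8.3) and read 319.5 ± 227.1 in mutants, at least 8.865-fold higher. Clca3 (today's Clca1), an abundant goblet cell product, fell from 6406 ± 1580 to 2872 ± 1958 (log2 difference -1.33, SE 0.31, adjusted p = 0.0164), with 5 of 6 mutants below the control mean and mutant 4 at 6693.8. That call ended without background correction (adjusted p = 0.0531) and without control 4 and mutant 1 (0.0552). Tff3, a mucus-associated peptide, read 4246 ± 1099 and 3851 ± 226 (adjusted p = 0.747). Of the secretory regulators, Spdef was at 82.4 ± 23.9 and 122.6 ± 26.3 (adjusted p = 0.0733), past the threshold only with sex as a covariate (0.0228) or without mutant 2 (0.0366). Klf4 was at 509.8 ± 121.3 and 472.0 ± 77.8 (adjusted p = 0.789), and Atoh1 lay within the noise limit in both groups.

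Enteroendocrine genes went both ways, with 2 of 21 higher and 4 lower (camera adjusted p = 0.861, the same numbers adjusted over the list alone). The gut hormones Pyy and Cck fell from 544.4 ± 149.1 to 189.0 ± 60.1 and from 1084 ± 315 to 647.8 ± 127.4, whereas the neuropeptide precursor Tac1 rose from 191.9 ± 33.5 to 374.6 ± 79.1. The transcription factor Nkx2-2 rose from 43.8 ± 8.9 to 65.8 ± 7.8, and the calls of Cck and Nkx2-2 ended without control 4 and mutant 1 (adjusted p = 0.0507 and 0.0662). Chga read 128.9 ± 26.5 and 158.4 ± 34.3 (adjusted p = 0.312). Among 13 tuft cell genes Plcg2 and Alox5ap rose, from 191.0 ± 15.0 to 316.6 ± 58.7 and from 150.1 ± 42.9 to 342.1 ± 86.5, and the list did not pass (camera adjusted p = 0.295, 2 adjusted over the list alone).

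Absorptive enterocyte genes did not shift as a list, though some members rose. Of 25 genes 5 rose and none fell (camera adjusted p = 0.585, median log2 difference -0.05). With adjustment over the list alone 4 more passed, all lower (Mep1a, Slc2a2, Apoc3 and Mttp). The row 2010204N08Rik, today's Sis or sucrase-isomaltase, rose from 306.2 ± 100.7 to 2328 ± 1769 (log2 difference 2.32, SE 0.45, adjusted p = 0.00538), every mutant lying above every control. The brush border protease Mep1b rose from 2151 ± 287 to 3727 ± 394 and the microvillus myosin Myo1a from 112.6 ± 34.7 to 308.0 ± 61.9. Enpep was called higher with both means within the noise limit. Suckling-type enterocyte genes, linked to the uptake and lysosomal breakdown of milk proteins before weaning, fell: 5 of 13 were lower and none higher (camera adjusted p = 0.0012, adjusted p = 0.158 with an estimated correlation, 6 adjusted over the list alone). Pdzk1ip1 fell from 2169 ± 404 to 1154 ± 256 and Amn, part of an endocytic receptor, from 12970 ± 1889 to 9908 ± 451. Neu1, a lysosomal sialidase, fell from 14280 ± 2504 to 8849 ± 2562, a call that ended without control 3, 5 or 6 or mutant 6 (adjusted p 0.0519 to 0.0614).

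In the stem cell list of 19 genes, 5 rose and 1 fell (camera adjusted p = 0.0854, 6 higher and 1 lower adjusted over the list alone). The stem cell receptor Lgr5 rose from 157.6 ± 29.0 to 314.2 ± 115.5 (log2 difference 0.71, SE 0.16, adjusted p = 0.0145), with no overlap between the groups. Olfm4, a secreted protein of crypt base cells, rose from 2070 ± 360 to 3614 ± 1285 (adjusted p = 0.0374). The Olfm4 call ended in 8 of the 12 fits that left out 1 mouse (control 3, 4, 5 or 6 or mutant 1, 3, 5 or 6, adjusted p 0.0562 to 0.0798). The receptor Ephb2 fell from 1238 ± 169 to 550.2 ± 91.7 (log2 difference -1.07, SE 0.11, adjusted p = 5.54e-05). The stem cell list itself passed without control 6, mutant 2 or mutant 4, at an adjusted p as low as 0.0171. Wnt target genes were mixed, 3 of 22 being higher and 2 lower (camera adjusted p = 0.317, 4 higher and 3 lower adjusted over the list alone). The transcription factor Sp5 rose from 69.4 ± 22.7 to 384.8 ± 139.4, while Notum, a secreted Wnt inhibitor, fell from 89.3 ± 24.3 to within the noise limit (13.4 ± 10.1), at least 3.125-fold lower. Axin2, Tcf7l2 and Ctnnb1 did not pass, at adjusted p of 0.3, 0.307 and 0.0997.

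Transcripts used as a readout of ERK signalling, the pathway downstream of Shp2, showed no shift as a group: 2 of 26 rose and none fell (camera adjusted p = 0.861, median log2 difference 0.00, 2 adjusted over the list alone). The 2 were Fos, from 531.2 ± 160.4 to 878.9 ± 201.4, and Ccnd1, from 937.3 ± 63.8 to 1203 ± 198. Fos lost its call without control 3, mutant 3 or mutant 6 (adjusted p 0.0541 to 0.0569), and Ccnd1 without any 1 control or mutant 1, 5 or 6 (0.052 to 0.0873). The ERK-induced phosphatase Dusp6 read 1724 ± 211 and 1401 ± 368 (log2 difference -0.31, SE 0.14, adjusted p = 0.21), past the threshold without mutant 4 (0.0483). Spry2 lay within the noise limit in both groups. Of 17 Notch pathway genes only Nrarp changed, falling from 1734 ± 191 to 1375 ± 190 (camera adjusted p = 0.295 for the list, 1 adjusted over the list alone). Its call ended in 9 of 12 fits that left out 1 mouse (control 3, 4, 5 or 6 or mutant 1, 2, 3, 5 or 6, adjusted p 0.058 to 0.0848). Hes6 read 487.8 ± 61.4 and 581.6 ± 52.6 (adjusted p = 0.0942, and 0.0497 without control 4). Proliferation genes rose in small steps: 5 of 23 were higher and 1 lower (camera adjusted p = 3.7e-05, adjusted p = 0.231 with an estimated correlation, 10 higher and 1 lower adjusted over the list alone). The mitotic genes Birc5 and Plk1 rose from 549.4 ± 83.8 to 898.8 ± 138.7 and from 464.7 ± 94.1 to 653.4 ± 58.4, and the replication licensing gene Mcm2 fell from 1001 ± 79 to 758.9 ± 109.0.

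Among metabolic genes, cholesterol synthesis rose and fatty acid oxidation fell. For cholesterol synthesis 4 of 16 members were higher and none lower (camera adjusted p = 2.03e-05, adjusted p = 0.218 with an estimated correlation, 5 adjusted over the list alone). Sqle, squalene epoxidase, rose from 806.4 ± 195.9 to 1406 ± 216, Cyp51 from 650.2 ± 122.3 to 1036 ± 196, Mvd from 262.8 ± 63.1 to 434.8 ± 84.7 and Fdps from 2139 ± 394 to 3325 ± 633. Of 20 fatty acid oxidation genes 5 fell and none rose (camera adjusted p = 0.000127, adjusted p = 0.218 with an estimated correlation, 8 lower and 1, Angptl4, higher adjusted over the list alone). The lipid droplet protein Adfp fell from 2709 ± 216 to 1688 ± 409. In the list of genes typical of the proximal small intestine, 4 of 10 fell and none rose (camera adjusted p = 4.79e-05, adjusted p = 0.0338 with an estimated correlation, 6 adjusted over the list alone). Among them were Cybrd1, a duodenal ferric reductase, from 76.7 ± 17.3 to 43.3 ± 11.3, and the hormone genes Cck and Gip. Gip went from 342.7 ± 115.8 to 193.3 ± 58.0, and its call ended without control 1, 2 or 3 or mutant 2, 4, 5 or 6 (adjusted p 0.0624 to 0.0901). Genes typical of the distal small intestine did not rise in turn, with 1 of 11 higher and 2 lower (camera adjusted p = 0.144, 1 higher and 3 lower adjusted over the list alone). Pyy and the bile acid transporter subunit Osta fell, the latter from 8563 ± 499 to 6880 ± 255, and the transcription factor Osr2 rose from 473.0 ± 151.0 to 1223 ± 427, with mutant 4 at 371.6. The Osr2 call ended without background correction (adjusted p = 0.0557) and without control 4 and mutant 1 (0.0662).

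Stress and timing programmes did not pass as lists. In the amino acid response list 3 of 16 rose and 1 fell (camera adjusted p = 0.598, 4 higher and 2 lower adjusted over the list alone). Asns, asparagine synthetase, rose from 385.8 ± 89.1 to 703.2 ± 62.2, the serine synthesis genes Phgdh and Psat1 from 59.6 ± 8.4 to 113.6 ± 25.1 and from 334.0 ± 94.5 to 523.0 ± 69.6, and Stc2 fell from 466.1 ± 64.4 to 297.8 ± 33.9. Of 16 unfolded protein response genes 2 fell (camera adjusted p = 0.63, 2 adjusted over the list alone). They were Dnajb9, from 2509 ± 580 to 1449 ± 398, and Ddit3, from 757.5 ± 242.0 to 451.6 ± 93.8, the latter losing its call without control 1, 3, 5 or 6 or mutant 1, 5 or 6 (adjusted p 0.0507 to 0.0736). Among 10 heat shock genes Bag3 alone rose, from 1302 ± 290 to 1946 ± 257 (camera adjusted p = 0.63 for the list, 1 adjusted over the list alone). Bag3 lost its call without mutant 3 or mutant 6 (adjusted p 0.0536 and 0.0564), and Hspd1 read 2025 ± 460 and 2551 ± 364 (0.161). Tef and Per2 fell, from 219.2 ± 37.5 to 109.4 ± 30.7 and from 1882 ± 182 to 1310 ± 200, among 14 clock genes (camera adjusted p = 0.195, 2 lower and 1, Per1, higher adjusted over the list alone).

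Interferon response genes were lower in the mutants. Of 22 members 5 fell and none rose (camera adjusted p = 6.7e-05, adjusted p = 0.4 with an estimated correlation, 9 lower and 1, Psmb8, higher adjusted over the list alone). Ifit3 fell from 2199 ± 851 to 748.6 ± 285.5 and Rsad2, an antiviral enzyme, from 3016 ± 1429 to 1107 ± 500. Oasl2 fell from 2093 ± 394 to 1250 ± 338 and Zbp1 from 77.3 ± 9.8 to 52.2 ± 8.3. The Rsad2 call ended without control 5, control 6 or mutant 6 (adjusted p 0.0538 to 0.0574), without background correction (0.0751) and with trend and robust variances (0.0668). Macrophage genes went both ways, 3 of 17 higher and 3 lower (camera adjusted p = 0.56, 3 higher and 3 lower adjusted over the list alone). The surface receptors Emr1 and Clecsf12 (Clec7a) fell from 185.7 ± 11.2 to 106.8 ± 15.8 and from 142.6 ± 41.5 to 56.7 ± 17.5, while the endotoxin receptor Cd14 rose from 60.7 ± 7.9 to 226.5 ± 112.0 and Cd163 from 1.8 ± 2.6 to 28.2 ± 12.2, close to the noise limit. Of 7 MHC class II genes H2-DMa passed, at 557.9 ± 161.2 and 795.9 ± 110.0, and lost its call in 9 of the 12 fits that left out 1 mouse (control 1, 2, 3 or 4 or mutant 1, 3, 4, 5 or 6, adjusted p 0.0538 to 0.0956). That list gave a camera adjusted p of 0.195 with 2 higher and 1 lower (H2-Aa) adjusted over the list alone, passing without control 6 (0.0338), and Cd74 read 3369 ± 647 and 4529 ± 688 (0.064; 0.0223 without control 6 and 0.0212 without mutant 6). None of 16 T and B lymphocyte genes or of 13 mast cell and eosinophil genes passed (camera adjusted p = 0.598 and 0.295, limma on single genes, 0 adjusted over either list alone). In the first, Cd4 lay within the noise limit in both groups, and in the second Cpa3 read 51.9 ± 7.5 and 70.4 ± 23.0 and Ear2 47.5 ± 8.3 and 57.1 ± 9.0.

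Endothelial genes were slightly lower, with 3 of 12 down and none up (camera adjusted p = 0.0183, adjusted p = 0.271 with an estimated correlation, 4 adjusted over the list alone). Emcn fell from 1704 ± 161 to 1342 ± 140, Tek from 679.2 ± 75.1 to 519.4 ± 88.3 and Egfl7 from 1506 ± 136 to 1257 ± 113. Tek and Egfl7 lost their calls in 7 and 10 of the 12 fits that left out 1 mouse, at adjusted p up to 0.0758 and 0.0964: Tek without control 3, 4 or 6 or mutant 1, 3, 5 or 6, and Egfl7 without any 1 mouse but control 4 and mutant 3. Emcn lost its call without control 4 and mutant 1 together (0.0576). The list fell short without control 4 and mutant 1 (adjusted p = 0.0789) and among rows above the noise limit (0.0521). Smooth muscle, fibroblast and enteric neuron lists stayed short of the threshold, with camera adjusted p of 0.0683, 0.0672 and 0.089. Of 13 smooth muscle genes Cnn1 rose (41.6 ± 8.3 to 68.6 ± 18.2) and Tagln read 419.1 ± 41.1 and 563.8 ± 131.5 (adjusted p = 0.0636, and 0.0326 without mutant 2), with 2 adjusted over the list alone. Of 17 fibroblast genes Lum rose, from 1282 ± 154 to 2014 ± 542, and Col5a1 read 3403 ± 492 and 4566 ± 1002 (0.0877; 0.0269 without mutant 2), with 1 adjusted over the list alone. Of 15 enteric neuron and glia genes Phox2a rose, from 109.5 ± 31.2 to 199.4 ± 47.4, Chat rose from 25.0 ± 4.7 to 44.7 ± 9.9, and S100b fell from 28.0 ± 11.1 to 0.4 ± 5.3 (control mean close to the noise limit), with 3 higher and 1 lower adjusted over the list alone. Cnn1 lost its call without control 1, 2, 3, 5 or 6 or mutant 3, 4 or 6 (adjusted p 0.0505 to 0.0812), Lum without mutant 1 (0.0503), and Chat without control 4 and mutant 1 (0.0547). These 3 lists passed when single mice were left out: smooth muscle without control 3 or 5 or mutant 1, 2 or 5 (as low as 0.0143), fibroblast without mutant 2 or 4 (as low as 0.0104), and enteric neuron without mutant 4 (0.0315).

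Transcripts of neighbouring organs were present in some mice. Of 21 pancreatic acinar genes only Reg1 passed, rising from 4291 ± 6326 to 14520 ± 4781 (log2 difference 2.55, SE 0.55, adjusted p = 0.0103; camera adjusted p = 0.856 for the list, 1 adjusted over the list alone). The large control spread came from control 4, at 17025.0 against 1063.2 to 3838.1 in the other controls. In mutants 3 to 6 Reg1 read 9892.4 to 16839.6 while Ela2a read -7.8 to 7.4. Controls 1, 2, 3 and 6 read 1063.2 to 1359.2 for Reg1 with Ela2a at -1.5 to 16.3. Reg1 was thus present in these mice, and high in those mutants, without that acinar transcript. Ela1 read 1768 ± 875 and 999.6 ± 402.8 (adjusted p = 0.108), and fell past the threshold without mutant 1 (0.0384) or without both control 4 and mutant 1 (0.0245). Without control 4, the acinar list was higher in the mutants (camera adjusted p = 0.0497), but mutant 1 stayed in that fit. Its mean log2 level of the list was 10.92, against 7.29 to 8.36 in the other mutants and 7.07 to 9.05 in the remaining controls. Without both control 4 and mutant 1 the list was far from the threshold (camera adjusted p = 0.874). Of 13 stomach and Brunner gland genes, 1190003M12Rik (today's Gkn3) fell from 90.6 ± 15.7 to 26.7 ± 19.5, and Atp4a was called higher with both means within the noise limit (camera adjusted p = 0.63, 2 higher and 1 lower adjusted over the list alone). Atp4a lost its call without control 1, 2, 3 or 5 or mutant 1, 3, 5 or 6 (adjusted p 0.0627 to 0.0965).

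The floxed allele and the Cre transgene can carry flanking donor-strain sequence in a mixed background, so genes next to Ptpn11 and Vil1 were counted separately. Of 52 tested genes within 50 annotated genes on each side of Ptpn11, 4 (7.7%) changed, against 9.2% of all others (Fisher's exact test, two-sided p = 1). The 4, named here after their values were seen, were Rasal1, C330023M02Rik, Oas1c and Trafd1. Rasal1, a RAS GTPase-activating protein, rose from 39.8 to 166.4 (limma adjusted p = 9.27e-06). Around Vil1 the count was 4 of 49 (8.2%, Fisher's exact test, p = 1). In every alternative fitted the share near Ptpn11 was instead above that elsewhere, with the smallest p from array weights and from sex as a covariate (Fisher's exact test, p = 0.019 and 0.0275).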

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

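Both groups of each named gene (250 groups of 6 mice, 125 genes) were searched for a single mouse far from the other 5. Chance alone gives such a gap in about 1 of 20 groups, and 12 were found. All tests of explanations in this part were chosen after the result was seen.

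The clearest case was Dao1, D-amino acid oxidase, with control 5 at -0.7 (other controls 837.6 to 1430.4) and mutant 1 at 402.8 (other mutants -1.3 to 8.8). An exchange of labels between these 2 mice was argued against, since 0 of the 2 correlated better with the mean of the other group over all genes. Dao lies on the chromosome of Ptpn11 with 188 annotated genes between them, so a stretch of donor-strain chromosome around Dao that mostly travels with the floxed allele may set its level. Near Dao 1 of 33 genes followed its residuals (absolute correlation over 0.7) against 60 of 9696 elsewhere (Fisher's exact test, two-sided p = 0.188). That 1 was the dim row 4930515G01Rik, 25 annotated genes from Dao, with a correlation of 0.91. It read -2.3 in control 5 and 27.3 to 58 in the other controls, and 43.9 in mutant 1 and -4.2 to 3.8 in the other mutants. Near Ptpn11 0 of 36 followed, and over the whole chromosome 8 of 646 did, of either sign (Fisher's exact test, p = 0.0624). These few rows leave a linked stretch open. The comparison of mutant with control cannot separate an effect of the mutation on Dao1 from that of a linked stretch.

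In the other cases 1 mouse stood apart and no explanation was tested. Control 1 was high for Ctnnb1 (3688.4, others 3024.5 to 3250.2) and for the alpha-defensin Defcr5 (321.5, others 27.4 to 82.7), and low for the stem cell list member Igfbp4 (1555.5, others 2487.7 to 2657.8), the collagen Col5a1 (2480.1, others 3320.3 to 3841.9) and the co-chaperone Bag3 (725.9, others 1326.7 to 1501.8). Mutant 3 was low for the receptor Ephb2 (377.7, others 545.7 to 633.2) and for Zbp1 (36.2, others 51.9 to 58.2). Mutant 4 was low for the distal marker Osr2 (371.6, others 1236.1 to 1488.9). Mutant 6 was low for Cd74 (3266.6, others 4477.8 to 5272.9) and for the stress gene Ddit3 (286.9, others 421.7 to 536.1).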

How the results depend on the processing

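The offset of 16, the filter at the noise limit and the removal of control 4 with mutant 1 were chosen after seeing the data. Calls ranged from 1218 without background correction to 1862 with array weights, and from 1247 (without mutant 3) to 1694 (without mutant 2) when 1 mouse was left out. In none of these fits did a shared call change sign. Without background correction 697 genes changed at least 1.5-fold and 317 at least 2-fold, against 431 and 138 in the report. That fit had no offset and set values under 1 to 1, so differences of dim genes were not shrunk in it. The offset of 16 alone gave 582 and 188. How much of the rest came from the missing offset and how much from the floor at 1 was not separated.

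Of the 11 lists, 2 stayed past the threshold with the correlation estimated from the data, Paneth cell and proximal identity. The others were epithelial defence (adjusted p = 0.0662), neutrophil (0.0786), goblet and suckling-type (both 0.158), cholesterol synthesis and fatty acid oxidation (both 0.218), proliferation (0.231), endothelium (0.271) and interferon response (0.4). A larger correlation is not the only cause: the estimated correlation of proximal identity (0.004) lay under the preset 0.01, yet its adjusted p was higher (0.0338 against 4.79e-05). What else raised these values was not tested. With fry, interferon response fell short (0.0706), and distal identity (0.0128), circadian clock and erythroid (both 0.0172) and Notch (0.0463) passed as lower. Endothelium also fell short above the noise limit (0.0521) and without control 4 and mutant 1 (0.0789).

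The erythroid list passed as lower with trend and robust variances (0.0466), array weights (0.0268), sex as a covariate (0.036), the offset of 16 (0.0489) and the noise filter (0.0248). Smooth muscle passed without control 4 and mutant 1 (0.0352). Lists far from the threshold changed direction: ERK/MAPK without background correction (0.979) and, like enteroendocrine and pancreatic acinar, with array weights (0.957 each), acinar also without background correction (0.871), above the noise limit (0.95) and without control 4 and mutant 1 (0.874), and stomach and Brunner gland above the noise limit (0.925). Without that pair Vil1 and Spry2 changed sign at log2 differences of 0.00443 and 0.000172. The cause of these changes was not tested.

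Near Ptpn11 the share of changed genes was below that elsewhere with the settings of the report, and above it in every alternative fitted: p = 0.019 with array weights, 0.0275 with sex, 0.262 above the noise limit, 0.459 with trend and robust variances, 0.596 without control 4 and mutant 1, 0.612 with the offset of 16, 0.778 without background correction and 0.81 with median scaling (Fisher's exact test). Near Vil1 it turned without background correction (0.571) and in 9 of the 12 fits that left out 1 mouse (all but those without control 1, control 4 or mutant 2). The counts near each gene are small, and the cause was not tested.

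Among the named genes, 24 calls ended without background correction: Bag3, Ccnd1, Cdc20, Clca3, Cnn1, Dao1, Ddit3, Egfl7, Eraf, Fos, Gip, H2-DMa, Hadhb, Igfbp4, Irf7, Lum, Neu1, Nox4, Nrarp, Olfm4, Osr2, Rsad2, Slc12a2 and Tek, at adjusted p up to 0.137. Without control 4 and mutant 1 the 19 that ended were Atp4a, Cck, Ccnd1, Cdc20, Chat, Clca3, Cpt2, Ddit3, Emcn, H2-DMa, Igfbp4, Neu1, Nkx2-2, Nox4, Nrarp, Olfm4, Osr2, Slc12a2 and Tek, at adjusted p up to 0.137. Calls also ended for Cnn1, Dao1 and Nox4 with array weights, Dao1, Egfl7 and Rsad2 with trend and robust variances, Egfl7 with median scaling and with sex, and Ccnd1, Egfl7 and Nrarp with the offset of 16. Cd74 passed with trend and robust variances (0.0445), sex (0.0439) and the noise filter (0.0437), and Tagln with that filter (0.0456).

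With 1 mouse left out, the lowest and highest values were 0.178 and 0.252 for the log2 difference of Ptpn11, -0.172 and 0.0212 for Tff3, -0.0431 and 0.0279 for Spry2, and -0.0484 and 0.000401 for Atoh1. Adjusted p ran from 0.0171 to 0.221 for the stem cell list, 0.0143 to 0.36 for smooth muscle, 0.0104 to 0.213 for fibroblast, 0.0315 to 0.19 for enteric neuron, 0.017 to 0.14 for erythroid, 0.0338 to 0.388 for MHC class II, 0.272 to 0.936 for T and B lymphocyte, 0.554 to 0.99 for ERK/MAPK, 0.667 to 0.984 for enteroendocrine and 0.0497 to 0.943 for pancreatic acinar. The Fisher p ran from 0.0555 to 0.813 near Ptpn11 and from 0.218 to 1 near Vil1.

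Both groups share replicate numbers, but no general pairing by number was seen. Deviations of same-number mice correlated at -0.097 to 0.232, with 2 pairs over 0.1, and 4 of 12 mice were closest to their own number. A pairing of some of the mice is not excluded by these values. The replicate block gave 1702 calls, 1422 of them shared with the 1663 of the report. With it Ptpn11 passed as higher (log2 difference 0.214, limma adjusted p = 0.044, 6 of 6 mutants above the control mean), as did the smooth muscle (0.028) and fibroblast (0.0441) lists, and the erythroid list as lower (0.0324). The calls of Nkx2-2 (adjusted p = 0.05), Cpt2 (0.0537), Cck (0.0571), H2-DMa (0.0632), Irf7 (0.065) and Ccnd1 (0.0885) ended with it, and Ela1 (0.0381, lower) and Hes6 (0.0465, higher) passed. Near Ptpn11 and Vil1 the Fisher p was 0.336 and 0.806, both with the larger share near the gene.

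Settings named before the data were examined and not run were the non-normalized source, filters on detection p, a slide block and averaging of probes, since no detection p and no slide was tied to a mouse and each gene had 1 value. The normexp alternative with an offset of 50 and that without a filter are the settings of the report. Signal over background limits the 7888 genes with both means at or under the noise limit of 27.8, among which 58 calls were made.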

Other observations

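The genes in this part, and all tests but that of the growth genes, were chosen after values were seen. Several genes not in the fixed lists, or not named from them, stood out, and no list of them was tested. Gpx2, a glutathione peroxidase, rose from 2638 to 8703, the cytokine Il18 from 414.7 to 1619, Hsd11b1, which activates glucocorticoids, from 93.5 to 1321, the complement protein C4b from 132.1 to 727.0 and the iron-binding Lcn2 from 81.6 to 1341. The alpha-defensin rows Defcr20 and Defcr6, which were not matched to the Paneth cell list, rose from 1094 to 13360 and from 1577 to 5219. In the other direction, the protease inhibitors Serpina1a to Serpina1e all fell, Serpina1b from 10490 to 4944, and so did Ttr, a thyroid hormone carrier, from 7516 to 3284. Each of these genes had an adjusted p of at most 0.0357 in every alternative fitted.

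Some genes had 2 separate levels that did not follow the groups. A gap of at least 2 log2 units was found in 47 genes, 17 of which followed the groups and 30 of which did not. Of these 30, 14 were high only in control 4 and mutant 1, and they included the trypsinogen Try10 (8348.8 and 6093.9). Tmem87a lay between 333.3 and 421.0 in controls 3 and 4 and mutants 1 and 4, and at or below 26.9 in the rest. Isx, an intestinal homeobox gene, lay between 111.9 and 120.9 in controls 5 and 6 and mutant 6, and at or above 701.7 in the rest. Mutant 5 alone had low Psmb9 (56.5) and Bat5 (21.0), and mutant 1 alone had high Defcr4 (15808.0). H2-Aa had no such gap, but was also lowest in mutant 5 (2.8), with the other mutants at 182.7 to 508.7.

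Ptpn11 was not lower in the mutants. Single samples with the wrong label were argued against, since 0 of the 12 mice correlated better with the mean of the other group. A probe outside the deleted part, or RNA of cells without Cre, could leave its level as it was. The log2 difference was 0.21, and this explanation stays open because the position of the probe is not given in the sources used here.

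Higher Paneth cell, defence, Sis and Arg2 transcripts (Arg2, an arginase, from 75.8 to 736.9) with lower suckling-type transcripts resemble the change at weaning. Every sample of both groups was labelled P6, so a later age of the mutant samples would go against their labels. It was tested all the same. The test, written before its result was seen, was the median log2 difference of 15 growth genes that fall after birth. It was 0.04, above the bound of -0.1 set beforehand as speaking against a later age. Members ran from -0.64 to 0.67 (SD 0.33), 1 called higher and 3 lower, so the median did not clear that bound by more than their spread. That comparison with the spread was added after the result was seen, and with it the explanation was read as open instead of excluded. The spread is that of single genes, not the uncertainty of their median. With it only a median well above 0 would have spoken against a later age. A difference of a few days was not tested. A more distal piece taken from the mutants could also contribute. The 6 distal genes above the noise limit had a median of -0.28, with 1 called higher and 2 lower, while the proximal list fell, so that this cannot be told apart from an effect of the mutation.

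For the number of changed genes, chance as the whole cause was excluded: of 100 splits of the 12 mice into 6 and 6, drawn from 462, only the real one (1 of 100) gave as many calls. It gave 1663, and the highest other split gave 5.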
